A study of Danio rerio with 3 samples.

How the data were processed

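The measurements were whole-larva gene expression profiles of zebrafish (Danio rerio) on an Affymetrix zebrafish array, which reads each transcript with a probe set, a group of short probes whose signals are combined. Per the labels, groups of 30 embryos were kept in cups with 100 ml of medium whose floor had been coated with 250 mg of oil emulsion. The emulsion came from the Gulfport shoreline after the Deepwater Horizon blowout and contained sand and seawater besides its hydrocarbons, both alkanes and polynuclear aromatic ones (PAHs). One group was exposed from 0 to 48 h post-fertilization (hpf), called the early window here, and another from 48 to 96 hpf, called the late window. Control embryos were kept in medium without emulsion. After exposure the larvae were moved to clean medium, where they spent 144 h (early window) or 96 h (late window) before RNA was taken at 192 hpf. An exposure from 96 to 192 hpf is mentioned in the protocol and is not analysed here. There were 3 arrays, 1 per group. The number of larvae behind each RNA sample is not given in the sources used here.

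The deposited values are log2 expression values for 15617 probe sets, made with RMA (robust multi-array average) per the submitters' processing notes. RMA subtracts background, gives the arrays a common distribution of probe intensities and summarises the probes of each probe set on the log2 scale. Its software and version are not given in the sources used here. The array medians were 7.22 for control, 7.20 for the early window and 7.23 for the late window, and the deposited values were used without further normalization.

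Probe sets were named through the platform annotation dated 2016. Of the probe sets, 10802 had 1 gene symbol, 135 had several and 4680 had none. Entrez gene IDs matched 10718 of those with 1 symbol to a RefSeq gene table of the GRCz12tu assembly, which updated 1 symbol. No gene was named from a probe set with several symbols or none. Where several probe sets stood for a gene, the one with the highest mean over the 3 arrays was used. A gene was kept when the highest of its 3 values reached 7.21, the median of all deposited values. This left 5492 of 8793 genes, of which 1173 had several probe sets.

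With 1 array per group there is no spread between replicates, so no test was run and no p-value is given. Values are log2 differences between arrays, and a fold is 2 raised to that difference. Before the data were examined, a difference of 2-fold (1 on the log2 scale) was fixed as the size at which genes are counted, and 1.5-fold and 3-fold as alternatives. The genes to be named were fixed by rule. They are the 10 highest and 10 lowest genes of each comparison with control, leaving out clone names, and the 5 highest and 5 lowest between the exposure windows. They also include up to 4 members of each gene list with the largest absolute difference, the 5 highest and 5 lowest shared genes, and cyp1a, cyp1b1, cyp1c1, cyp1c2 and ahrra. For cyp1b1, cyp1c2 and ahrra no probe set carried that single symbol here.

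A total of 34 gene lists of pathways, tissues and cell types had also been written before the data were examined. For the 32 lists with at least 5 measured genes, the median log2 difference was placed among the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. A list is called above or below the random lists when its median lies over the 97.5th or under the 2.5th percentile. This describes these 3 arrays and is not a p-value. Random genes are less coregulated than the members of a pathway, so the percentiles overstate how unusual a list is. Of 96 list comparisons, 48 lay outside the middle 95% of random lists, against 4.8 for lists of independent random genes.

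Technical spread was read from 18 hybridisation spike-in probe sets and from 717 genes with several bright probe sets (1557 probe sets). Neither measure holds the spread between clutches of embryos or between RNA samples. Both comparisons with control use the same array, so their covariance and shared genes were set beside 1000 simulations of unchanged arrays that share a control.

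Gene counts, list medians and named genes were recomputed under the alternatives that apply to each. These were median centring, a second quantile normalization, a loess correction (span 0.3), no filter, a filter at the 75th percentile (8.48), the mean over probe sets, no cross-hybridising probe sets, unmatched random lists and lists without their most changed member. Named genes were recomputed only under the normalizations and the choices of probe sets, and those named only as members of a list were not recomputed. The removal of a list member, synonyms and unmatched random lists concern lists only. Scaling on spike-ins and list matching through gene synonyms were added after the data were seen. The counting and list steps were tested on simulated data for the late-window comparison with 5492 genes. All 72 genes shifted by 1.5 and all 57 shifted by 2.5 on the log2 scale were counted, as were 9 of 71 shifted by 0.8 and 0 of 5292 unchanged genes. The simulated differences had normal noise with an SD of 0.16, the robust spread between the exposed arrays. The observed SD for the late window was 0.23. At that noise a 2-fold size leaves out unchanged genes by construction, so the count of 0 gives no rate of false calls on real arrays. Of 200 random lists of 25 unchanged genes, 10 were called, and all 200 were called after a shift of 0.3. The percentile limits give about 5% of such lists by construction, and shifts smaller than 0.3 were not simulated. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, with R 4.3.3 and limma 3.58.1 for normalization.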

Results

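Zebrafish larvae were profiled at 192 hpf after exposure to shoreline oil emulsion in an early window (0 to 48 hpf) or a late window (48 to 96 hpf), beside unexposed larvae. Each group was measured on 1 array, so there are no replicates, and every value below describes those 3 arrays. Over 5492 genes, the values of the exposed and control arrays correlated at r = 0.993 across genes for the early window and 0.987 for the late window. Genes are not independent replicates. The SD of the log2 differences from control was 0.17 for the early window and 0.23 for the late window. Probe sets of the same gene varied around the mean of that gene with an SD of 0.11 and 0.16 in those comparisons.

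All directions are relative to the median gene of each array. The hybridisation spike-ins, bacterial transcripts added to every sample before hybridisation, read -0.50 on the early-window array against control (SD 0.12 over 18 probe sets) and 0.01 on the late-window array. On a spike-in scale the median gene of the early-window array would lie 0.50 above control, and all its differences would move up by that amount. Probe sets for sequences foreign to zebrafish had medians of 4.61 on the control array, 4.74 on the early-window array and 4.84 on the late-window array. The 3' minus 5' signal, a sign of RNA integrity, was 2.12, 2.02 and 2.28 for actin and 0.379, 0.432 and 0.342 for gapdh in the same order, so the 2 transcripts ranked the arrays in opposite ways.

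The first comparison asks which transcripts still differed from control at 192 hpf after exposure in the late window, 96 h after the larvae had been moved to clean medium. The largest differences were in enzymes of xenobiotic metabolism. The transcript of cyp1a, a cytochrome P450 that oxidises PAHs and is induced through the aryl hydrocarbon receptor (AHR), was 25.7-fold higher than control (log2 values 13.98 and 9.30). Its relative cyp1c1 was 11.7-fold higher, cyp2k18 8.07-fold higher and cyp3a65, a CYP3A enzyme of liver and intestine, 3.48-fold higher. In all, 17 genes were at least 2-fold higher and 5 at least 2-fold lower. With the filter at the 75th percentile or with the mean over probe sets, 2 genes were lower.

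All 6 measured genes of the AHR list were higher than control on the late-window array, with a median difference of 1.25, above all 10000 random lists. Besides cyp1a and cyp1c1 they were sult6b1, a sulfotransferase (log2 difference 1.52), tiparp, a repressor of the AHR (0.99), ahr2, the main AHR of zebrafish (0.77), and nqo1, a quinone reductase (0.54), which the naming rule leaves out and which completes the list. The median of the list was 0.99 without cyp1a, and 0.77 over 9 genes without the expression filter. All 10 genes of the CYP2 and CYP3 list, which includes pora, the reductase that supplies these enzymes with electrons (0.06), were also above control, with a median of 0.26 that exceeded 9998 of the random lists. Among them cyp2y3 differed by 0.61 and cyp2aa4 by 0.39. With the filter at the 75th percentile the median of the CYP2 and CYP3 list was 0.61. Of 14 conjugating (phase II) enzymes, 10 were higher (median 0.09), led after sult6b1 by the glutathione S-transferases gsto2 (0.96), gstt1b (0.87) and gstp1.2 (0.81). The median of that list no longer stood apart from random lists without the expression filter (0.06) or with the mean over probe sets (0.07).

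Genes of the oxidative stress response that Nrf2 controls were higher on the late-window array in 22 of 24 cases, with a median of 0.25, above all random lists. The largest differences were in prdx1, a peroxiredoxin (1.41), pgd, an NADPH-producing enzyme of the pentose phosphate pathway (0.93), gsr, glutathione reductase (0.89), and keap1a, the inhibitor of Nrf2 (0.55). Also at least 2-fold higher were alas1, the first enzyme of heme synthesis (1.51), cyb5a, cytochrome b5 (1.35), me1, the NADP-dependent malic enzyme (1.23), and opn1mw2, a green cone opsin (1.30). The rest of the 17, outside the naming rule and chosen after their values were seen to complete the count, were mao, monoamine oxidase (1.20), ces2b, a carboxylesterase (1.15), faxdc2 (1.12), mala.2 (1.07), ugdh, which makes UDP-glucuronate (1.03), and the clone-named wu:fj05g07 (1.44) and si:ch211-207n23.2 (1.25). Other bright probe sets read lower for mao (0.48 and 0.40) and ugdh (0.62), and with the mean over probe sets 15 genes were at least 2-fold higher. The malic enzyme gene me1 belongs to the list of sterol and fatty acid synthesis, whose median of 0.05 did not stand apart from random lists. In that list fdps differed by -0.61, elovl5 by -0.58 and elovl4b by -0.57.

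Cartilage, bone and matrix genes were lower than control on the late-window array in 30 of 40 cases, with a median of -0.20, below all random lists. Without the expression filter that median was -0.11, still below random lists. The members with the largest differences were hapln1a, a link protein of cartilage matrix (-0.91), sox9b, a regulator of cartilage formation (-0.71), col9a3, a chain of type IX collagen (-0.58), and cnmd, chondromodulin (-0.50). Other bright probe sets of hapln1a read -0.66 and -0.50, and that of cnmd -0.61. Epidermal genes were lower in 40 of 54 cases (median -0.10), with krt15, a keratin, 3.01-fold lower and anxa1c (-0.69), agr1 (-0.57) and krt91 (-0.54) next. Genes of ion and water transport had a median of -0.13 over 19 genes, with slc13a2 at -0.64 and the sodium pump subunit atp1a1a.3 at -0.51. This list no longer stood apart without the expression filter (-0.05) or with the filter at the 75th percentile (-0.11).

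Phototransduction genes were lower on the late-window array in 25 of 33 cases (median -0.21, below all random lists), among them the rod transducin subunit gnat1 (-0.89), gnb1b (-0.78) and rom1b (-0.69). The cone opsin opn1mw2 went the other way. Neuronal and glial genes had a median of -0.10 (47 of 62 lower), with inaa, a neuronal intermediate filament, at -0.55 and lhx8a at 0.64. Circadian clock genes had a median of -0.19 (17 of 23 lower), with cry2 at -0.71 and rorab at -0.42. In the liver list, written for secreted proteins but also holding proteins that act inside liver cells, 28 of 34 genes were higher (median 0.17). Its largest differences were in fabp10a, the liver fatty acid-binding protein (0.82), and hpda (0.61), neither of them secreted. Intestinal genes (median 0.11) included fabp6, an ileal bile acid-binding protein, at 0.84 and the bile acid transporter slc10a2 at 0.68. Erythroid genes had a median of 0.18, with tspo at 0.68 and slc4a1a at 0.46. Innate immunity genes had a median of 0.12, with mmp13a at 0.92, crp3 at 0.87 and cxcl12b at -0.64.

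The p53 and apoptosis list (0.07), the proteasome (0.06) and oxidative phosphorylation (0.05) also lay above random lists in the late window, by smaller amounts. Other genes at least 2-fold lower were ube2ql1, a ubiquitin-conjugating enzyme (-1.20), ankrd12 (-1.06), rsf1b.1 (-1.03) and the clone-named zgc:112964 (-1.63), which lies outside the naming rule and was chosen after its values were seen, because it completes a count of 5. Leaving out clone names, the next lowest were hapln1a (-0.91) and gnat1 (-0.89), given above, and then spon2b (-0.88), cadm3 (-0.83) and hsd17b8 (-0.82). The 2 bright probe sets of hsd17b8 disagreed (-0.82 and 0.25), and the mean over all probe sets put ube2ql1 at -0.53. With that mean, and with the filter at the 75th percentile, ankrd12 and rsf1b.1 were under the filter and have no value.

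**Figure D1:**
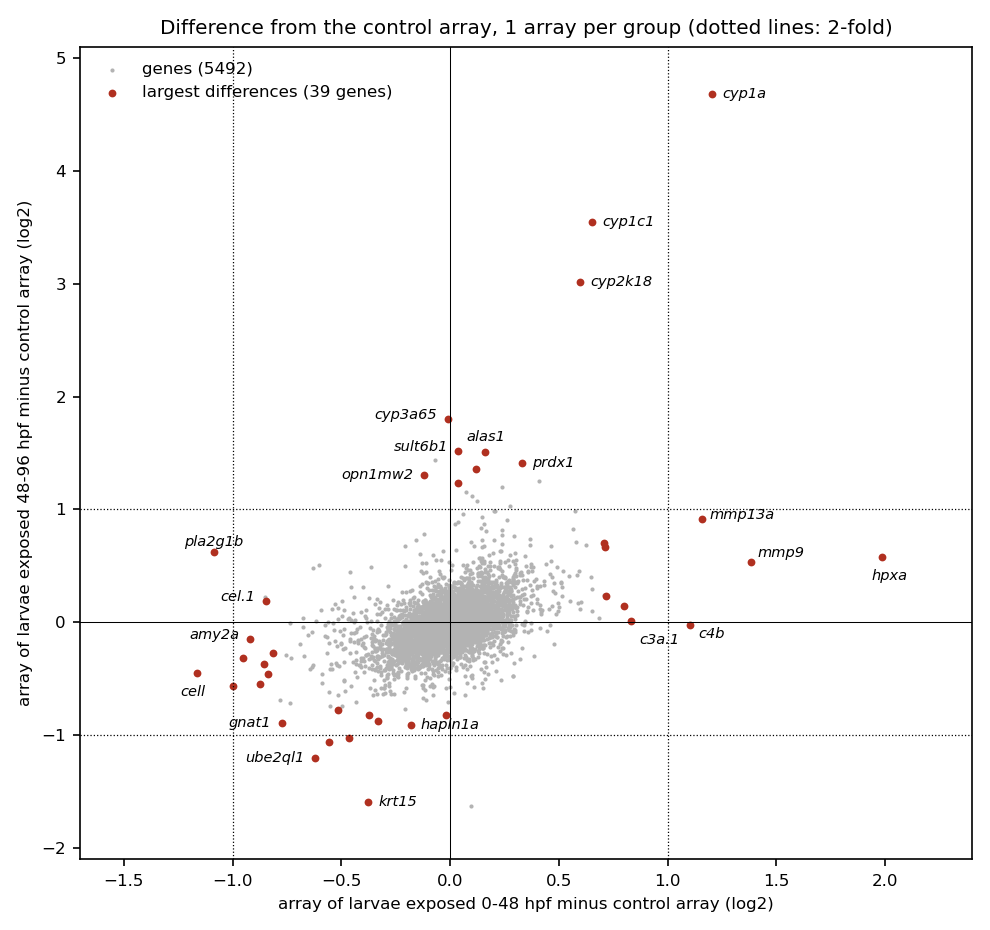
Log2 difference of 5492 genes (points) from the control array for the early (horizontal) and late window (vertical), with the largest differences in red and dotted lines at 2-fold. The highest genes were cyp1a (4.68) and cyp1c1 (3.54) in the late window and hpxa (1.99) in the early window, and on a spike-in scale all points would lie 0.50 further right.

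The second comparison asks the same for the early window, 144 h after transfer to clean medium. The largest difference was in hpxa, hemopexin, a plasma protein that binds heme, which was 3.97-fold higher than control (8.74 against 6.75 on the log2 scale, the latter a dim reading). The matrix metalloproteinases mmp9 and mmp13a were 2.61-fold and 2.23-fold higher, cyp1a 2.30-fold and the complement gene c4b 2.15-fold. Genes of digestive enzymes and of vision were lower than control. The 5 genes named were the only ones at least 2-fold higher, and 2 genes, pla2g1b, a pancreatic phospholipase (-1.09), and the gene with the symbol cell (-1.16), were at least 2-fold lower. On the spike-in scale the same counts were 35 higher and 0 lower.

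Exocrine pancreas genes, which encode digestive enzymes, were lower than control on the early-window array in 16 of 17 cases, with a median of -0.54, below all random lists. After pla2g1b the largest differences were in amy2a, amylase (-0.92), cel.1, a carboxyl ester lipase (-0.85), and sycn.2, a zymogen granule protein (-0.74). On the late-window array the same list had a median of 0.00 and 9 of 17 genes above control. Endocrine pancreas genes had a median of -0.11 on the early-window array, within the range of random lists, with sst2, somatostatin, at 0.65 and pax6b at -0.52. The intestine list had a median of -0.07, with chia.1 at -0.56 and rbp2a at -0.41, and its sign turned (to 0.0058, 0.017 and 0.019) under quantile normalization, the mean over probe sets and synonym matching, the last an alternative added after the data were seen.

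Genes of the eye were lower on the early-window array. Phototransduction genes were lower in 30 of 33 cases, with a median of -0.44, below all random lists. Their largest differences were in the cone phosphodiesterase pde6c (-0.86), guca1c, an activator of retinal guanylate cyclase (-0.81), rom1b (-0.78) and gnat1 (-0.77). All 7 lens genes were lower (median -0.36), including the crystallin cryaa (-0.59) and lctla (-0.57). Neuronal and glial genes had a median of -0.11 (48 of 62 lower), with inaa at -0.88, mbpa, a myelin basic protein, at -0.57 and nrgna at -0.51. Circadian clock genes had a median of -0.15 (19 of 23 lower), with cry2 at -0.74, nfil3-6 at -0.68 and bhlhe41 at -0.64. On the spike-in scale the medians of these lists would be -0.04 for exocrine pancreas, 0.06 for phototransduction, 0.14 for lens, 0.39 for neurons and glia and 0.35 for the clock, against 0.50 for the median gene. They would stay below the other genes but not below control, except exocrine pancreas.

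In the liver list, 28 of 34 genes were higher on the early-window array, with a median of 0.21, above all random lists. Besides hpxa they included the complement component c3a.1 (0.83) and the fibrinogen chains fgb and fga (0.71 each); the mean over probe sets put c3a.1 at 0.68. Complement gene c6.2 differed by 0.80. The innate immunity list had a median of 0.13 (19 of 25 higher), led by mmp9 and mmp13a, with socs3b, an inhibitor of cytokine signalling, at 0.65 while the chemokine ccl34b.1 was just under 2-fold lower. All 6 genes of the AHR list were above control (median 0.22, above 9994 of the random lists), with cyp1c1 at 0.65, ahr2 at 0.24 and tiparp at 0.21. The CYP2 and CYP3 list did not stand apart (median -0.01), with cyp2k18 at 0.60 and cyp2ad2 at -0.50.

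Smaller shifts above random lists on the early-window array were those of the Nrf2 list (0.09; taldo1 at 0.35 and prdx1 at 0.33), heat shock and ER stress (0.09; the chaperone hspa5 at 0.34), the proteasome (0.07), p53 and apoptosis (0.07) and oxidative phosphorylation (0.05). The Nrf2 list no longer stood apart without cross-hybridising probe sets (0.07), and the p53 list under 5 of 10 alternatives. The cartilage, bone and matrix list had a median of 0.00 in the early window. Other named genes were npm1b (0.71) and ctss2.1, a cathepsin S (0.71), both also above control on the late-window array (0.67 and 0.70). Lower were c6ast3, an astacin protease (-0.95), and pdca, phosducin (-0.84).

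**Figure D2:**
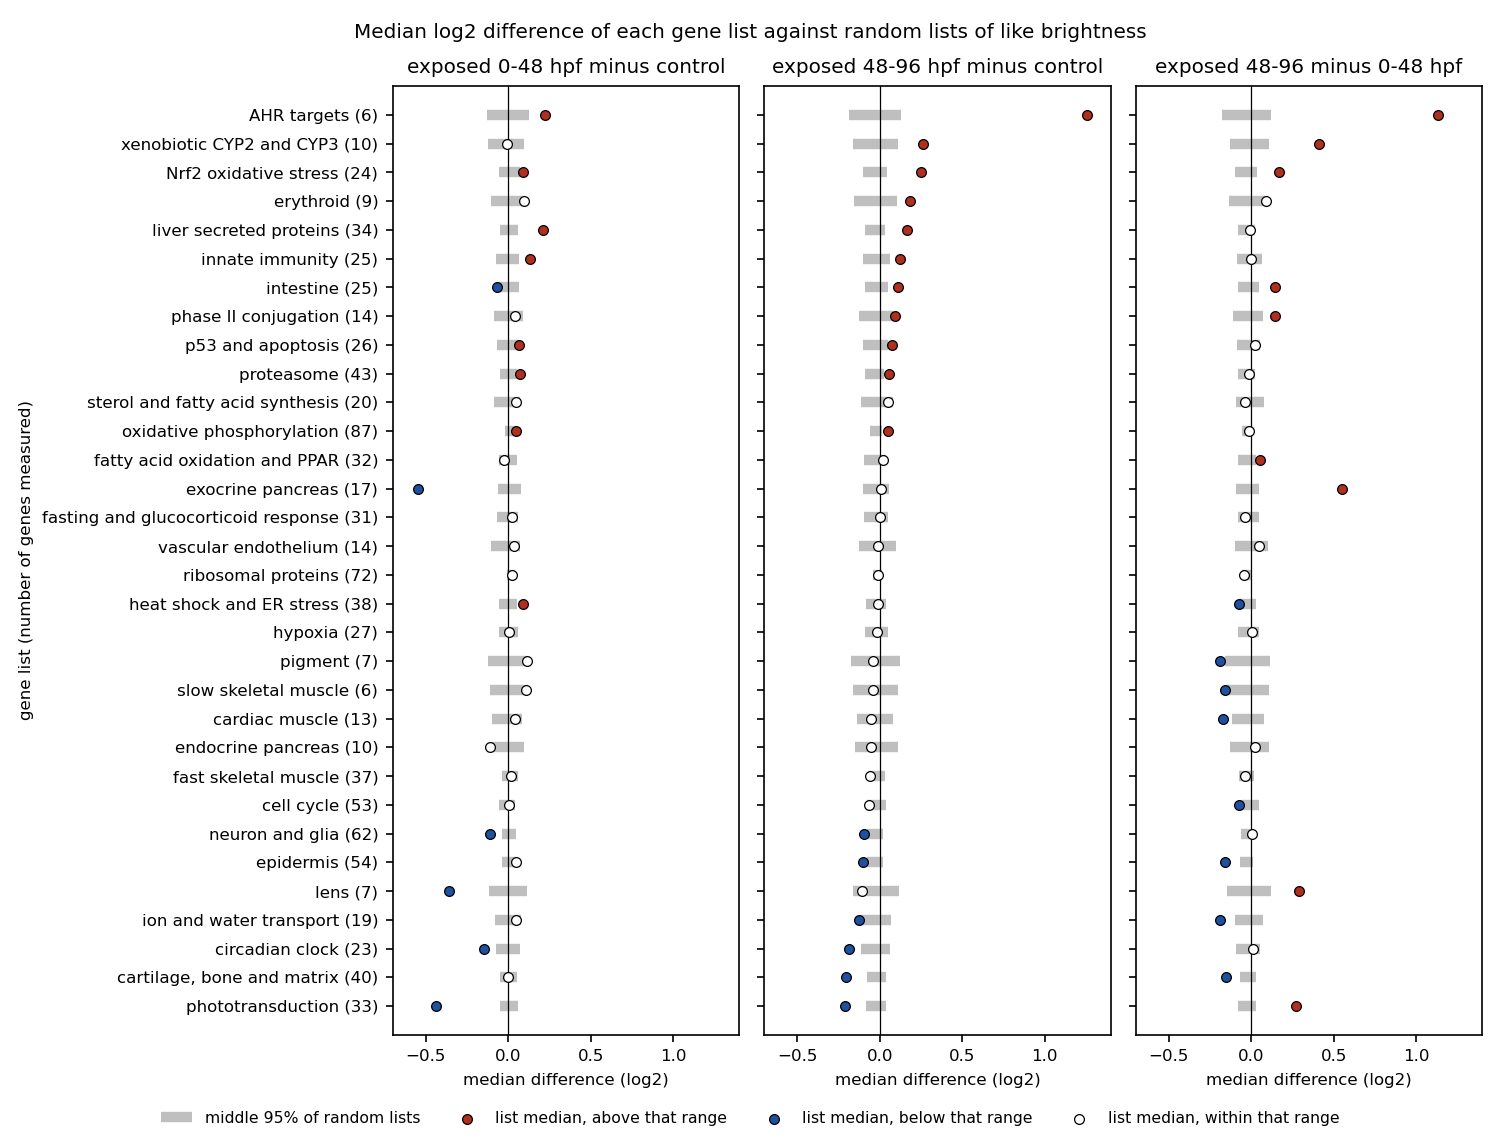
Median log2 difference of each of 32 gene lists (points) in the 3 comparisons, with the middle 95% of 10000 random lists of like brightness (grey bars). Exocrine pancreas lay furthest below random lists in the early window (-0.54) and AHR targets above them in all comparisons (0.22, 1.25 and 1.13), and on a spike-in scale points and bars would lie 0.50 further right in the left panel and 0.51 further left in the right panel.

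The third comparison sets the exposed arrays against each other and leaves the control array out. The late-window array was higher by 3.48 in cyp1a (11.2-fold), 2.89 in cyp1c1, 2.41 in cyp2k18, 1.81 in cyp3a65 and 1.71 in pla2g1b. It was lower in hpxa (-1.41), krt15 (-1.21), c4b (-1.13), mmp9 (-0.85) and c3a.1 (-0.82). In all, 18 genes were at least 2-fold higher and 4 at least 2-fold lower in the late window. On the spike-in scale these counts were 6 and 59.

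The AHR targets had a median of 1.13 between the windows, which was 0.78 without cyp1a and 0.61 without the expression filter. Above random lists were also exocrine pancreas (0.55, with 17 of 17 genes higher in the late window), the CYP2 and CYP3 list (0.41), lens (0.29), phototransduction (0.27), the Nrf2 list (0.17), phase II enzymes (0.15), intestine (0.14) and fatty acid oxidation (0.05). Below them were ion and water transport (-0.19), pigment (-0.19), cardiac muscle (-0.17), epidermis (-0.16), slow skeletal muscle (-0.16), cartilage, bone and matrix (-0.15), heat shock and ER stress (-0.07) and the cell cycle (-0.07). In the cardiac list myl7, an atrial myosin light chain that marks heart muscle, was at 0.21 in the early and -0.43 in the late window against control, and cmlc1 at 0.28 and -0.27. The chaperone of collagen serpinh1b was at 0.29 and -0.48. Heat shock and ER stress, cardiac muscle, slow skeletal muscle, cell cycle, pigment, ion and water transport and fatty acid oxidation each lost their place outside random lists under at least 1 alternative. On the spike-in scale every median in this comparison falls by 0.51, which leaves the AHR targets at 0.62 and exocrine pancreas at 0.04 and puts CYP2 and CYP3 (-0.10) and the other lists above below 0.

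**Figure D3:**
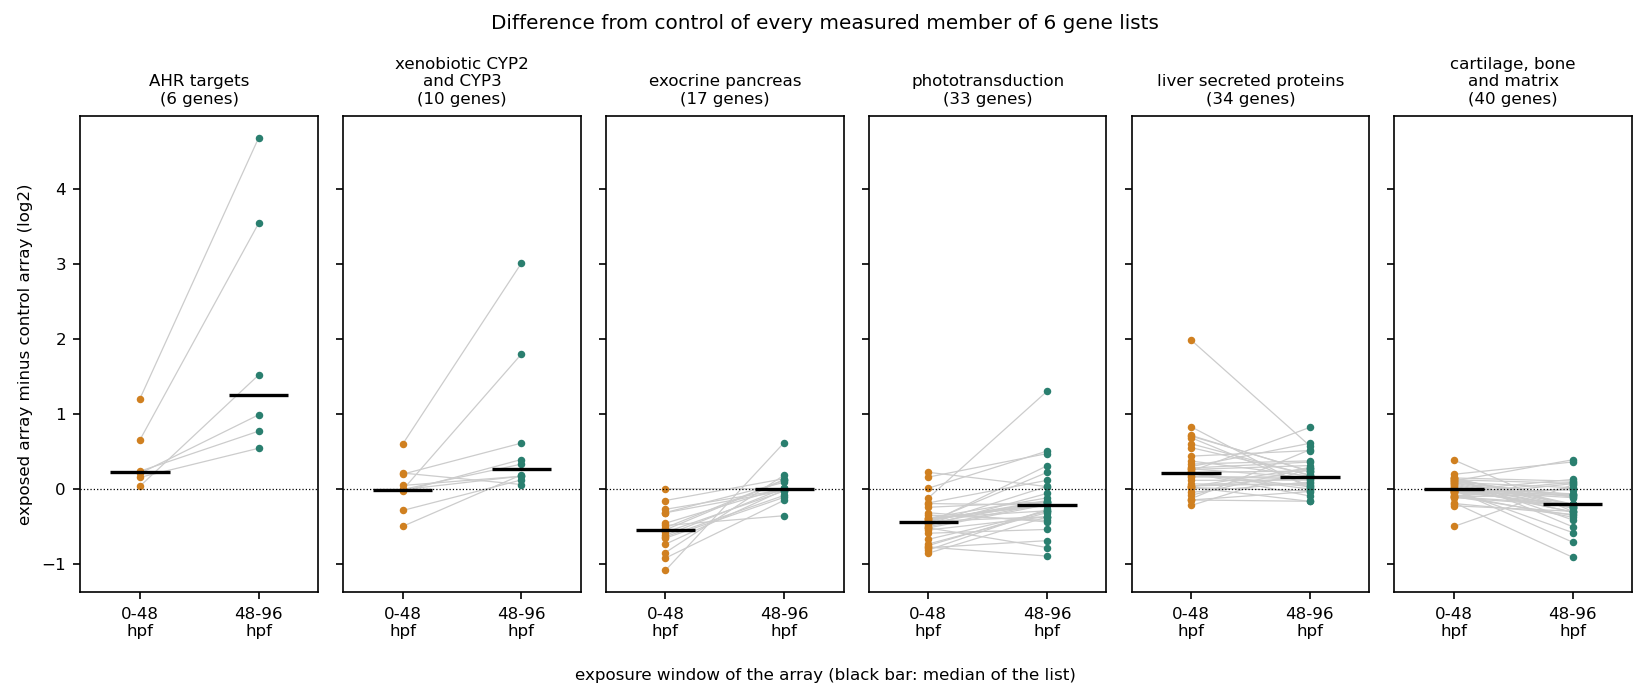
Log2 difference from the control array of each measured member of 6 gene lists (points, joined by gene) for the early and the late window, with the median of each list as a black bar. Medians were 0.22 in the early and 1.25 in the late window for AHR targets and -0.54 and 0.00 for exocrine pancreas, and on a spike-in scale the early-window points would lie 0.50 higher, with exocrine pancreas at -0.04 and phototransduction at 0.06.

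Because both windows were compared with the same control array, some likeness between them arises by chance. The differences from control correlated at r = 0.48 across genes (rho = 0.50), beside 0.50 for simulated unchanged arrays with a shared control. Their covariance was 0.0195 against 0.0121 in the simulation, and 67.6% of genes had the same sign, beside 66.6% in the simulation. The simulated noise was normal and set from a robust spread, so it leaves out large differences. It was equal on all arrays, and with a shared control this alone fixes the simulated correlation near 0.50. It likewise fixes the simulated share of genes with the same sign near 66.6%, whatever the data. The observed variances specific to each array, given below, were unequal. The likeness of the correlation and the sign share to the simulation therefore cannot tell whether the exposures shared effects. Over the 5351 genes within 1.5-fold of control in both windows the covariance was 0.0133. The variance specific to each array, read from the covariances, was 0.0195 for control, 0.0108 for the early and 0.0357 for the late window. At 2-fold, 1 gene was higher in both windows, cyp1a, and 0 were lower, against 0.0155 and 0.00182 for independent sets of genes and 0 in the simulation. At 1.5-fold, 7 genes were higher in both windows (0.244 for independent sets, 0.125 simulated) and 4 were lower (0.222 and 0.128). The 4 lower genes were gnat1, rom1b, cry2 and ube2ql1, and the higher ones included cyp1a, cyp1c1, cyp2k18 and mmp13a. With 1 control array the controls could not be split, so shared genes were not told apart from readings of that array. Some lists had like medians in both windows and lay within random lists between them. Relative to the median gene the exposed arrays differed by -0.0065 in the liver list, 0.0008 in innate immunity, 0.0047 in neurons and glia and 0.012 in the clock. They differed by -0.015 in the proteasome, 0.024 in p53 and apoptosis and -0.012 in oxidative phosphorylation. For these lists a control reading was not told apart from effects of both exposures.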

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

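The islet hormones of the pancreas were chosen as a comparison, and the brightness test below was written, only after the exocrine pancreas values had been seen. The gene of the pancreatic phospholipase pla2g1b had opposite signs in the exposure windows, with log2 differences from control of -1.09 for the early and 0.62 for the late window. The intestine list also had opposite signs, with medians of -0.067 and 0.11, but its early-window value ranged from -0.082 to 0.019 over 10 alternatives, 4 of which kept its place below random lists, and on the spike-in scale the medians were 0.43 and 0.10. These were singled out because they differed between the exposed groups, and with 1 array per group the differences were not tested.

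Exocrine pancreas genes as a list had a median of -0.54 on the early-window array (-0.04 on the spike-in scale). Genes of like brightness did not share this shift: among 10000 random lists as bright as the exocrine genes, the lowest median was -0.13. They are the lists that had already set this one apart, so they are no separate test of scaling by brightness. A smaller pancreas as a whole stays open. The islet hormones glucagon (gcga, 0.25), insulin (ins, 0.08) and somatostatin (sst2, 0.65) had a median of 0.25. Yet the endocrine pancreas list written beforehand had a median of -0.11 and fell below random lists under 4 of 10 alternatives. In it 7 of 10 genes were lower, among them pax6b (-0.52) and neurod1 (-0.32). Both also belong to lists of retinal genes that were lower on this array, so their values do not speak for the pancreas alone. Feeding, the amount of gut content and a delay in growth were not recorded and remain open.

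A further 1778 bright probe sets without a single gene name were left out of the gene counts. Of these, 4 were at least 2-fold higher and 1 at least 2-fold lower than control on the early-window array, and 7 were higher and 2 lower on the late-window array. That is 0.281% and 0.506% of them, beside 0.127% and 0.401% of named genes. The largest differences were 1.21 and 2.04 and the lowest -1.08 and -1.22. They are listed because no report was made on these probe sets, and their differences were not tested.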

How the results depend on the processing

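The lists that carry the comparisons kept their direction and their place among random lists under all 10 alternatives to the processing. Scaling on spike-ins is apart from these, since it moves a list and its random lists alike: it leaves their order and turns phototransduction in the early window to 0.06 and lens to 0.14 against control. AHR targets in the late window ranged from 0.77 to 1.29, exocrine pancreas in the early window from -0.56 to -0.52, and phototransduction from -0.46 to -0.42 in the early and from -0.22 to -0.18 in the late window. Cartilage, bone and matrix genes in the late window ranged from -0.24 to -0.11. Of the list medians under the alternatives, 898 kept their place within or outside random lists, 31 no longer stood apart and 19 newly did. A further 3 within random lists moved more in value, and 3 that had stood apart turned in sign. A median within random lists could change sign and still count as kept, as endocrine pancreas did in the late window (-0.12 to 0.05). With the 75th percentile filter the lens (3 genes) and vascular endothelium (4 genes) lists were too short to be placed. Of the gene counts, 58 stayed within 1.5 times the value reported and 22 did not. Of the values of the highest, lowest, shared and always named genes, 561 stayed, and 9 changed, all with the mean over probe sets. Genes named only as members of a list were not recomputed. The covariance of the comparisons with control stayed in all 5 cases.

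The number of genes lower in the late window was 2 with the 75th percentile filter and 2 with the mean over probe sets. At 1.5-fold, 22 genes were higher and 33 lower in the early window, 61 and 37 in the late window, 67 and 29 between windows, and 7 and 4 in both windows. At 3-fold these were 1 and 0, 4 and 2, 5 and 1, and 0 higher in both. Fold alternatives differ by construction. Scaling on the spike-ins, added after the data were seen, gave 35 higher and 0 lower in the early window, 6 and 59 between windows, and 3 higher in both. That shift follows from the spike-in reading of the early-window array, and the cause of the reading was not tested.

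In the lists that follow, medians are against control in the named window or between windows (late minus early). With the 75th percentile filter the medians that no longer stood apart were cardiac muscle (-0.11), cell cycle (-0.092) and heat shock and ER stress (-0.077) between windows, intestine (-0.070) and p53 and apoptosis (0.057) in the early window, and ion and water transport (-0.11) in the late window. Innate immunity between windows (-0.19), slow skeletal muscle in the early window (0.11) and sterol and fatty acid synthesis in the late window (0.11) newly stood apart, and pigment in the early window moved to -0.043. Without a filter the medians lost were cardiac muscle (-0.058), ion and water transport (-0.055) and pigment (-0.028) between windows, ion and water transport (-0.053) and phase II conjugation (0.060) in the late window, and p53 and apoptosis (0.050) in the early window. Cell cycle in the late window (-0.053) and neuron and glia between windows (0.040) were gained, and lens in the late window moved to 0.064.

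Quantile normalization turned intestine in the early window to 0.0058. It lost heat shock and ER stress (-0.051) and slow skeletal muscle (-0.14) between windows and p53 and apoptosis in the early window (0.080), and gained erythroid between windows (0.12) and pigment in the early window (0.14). Loess lost heat shock and ER stress between windows (-0.045) and p53 and apoptosis in the early window (0.077), gained pigment in the early window (0.13) and moved oxidative phosphorylation between windows to 0.02. Median centring lost heat shock and ER stress between windows (-0.10). The mean over probe sets turned intestine in the early window to 0.017 and lost p53 and apoptosis in the early (0.050) and phase II conjugation in the late window (0.073). It gained endocrine pancreas (-0.15), pigment (0.11) and sterol and fatty acid synthesis (0.073) in the early window and neuron and glia between windows (0.028).

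Without cross-hybridising probe sets, Nrf2 in the early window (0.069) and heat shock and ER stress between windows (-0.074) were lost, and pigment in the early window (0.11) was gained. Unmatched random lists lost fatty acid oxidation (0.051) and slow skeletal muscle (-0.16) between windows and intestine in the early window (-0.067), and gained endocrine pancreas (-0.11) and epidermis (0.047) in the early window. Without the most changed member, cardiac muscle (-0.11), heat shock and ER stress (-0.073), pigment (-0.14) and slow skeletal muscle (-0.15) between windows and intestine in the early window (-0.024) were lost, and endocrine pancreas in the early window (-0.14) was gained. Synonym matching, added after the data were seen, turned intestine in the early window to 0.019, lost heat shock and ER stress between windows (-0.073), and gained endocrine pancreas (-0.14) and erythroid (0.14) in the early window and neuron and glia between windows (0.015). For all of these the cause was not tested.

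No paired analysis was possible because each group had 1 array, and for the same reason leaving out an array and splitting the samples another way were not possible. An alternative log scale was not run because the deposited values were already on the log2 scale. Signal over background limits dim genes: foreign-sequence probe sets had a median of 4.61 on the control array, beside a median of 7.22 for all probe sets.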

Other observations

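Relative to the median gene, several groups of genes that mark growth and general condition lay close to control in both windows. Ribosomal protein genes had medians of 0.02 in the early and -0.01 in the late window over 72 genes, fast skeletal muscle 0.02 and -0.06 over 37 genes, and hypoxia genes 0.00 and -0.01 over 27 genes. Genes of fasting and the glucocorticoid response had medians of 0.03 and 0.00, and vascular endothelium 0.04 and -0.01. On the spike-in scale their early-window medians would be 0.53, 0.52, 0.50, 0.53 and 0.54 in that order, beside 0.50 for the median gene. None of these lists stood apart from random lists in any comparison. Random lists were drawn from all genes of like brightness, list members included. The ribosomal list, large and bright, was thus placed partly among its own members. Single members did differ, such as plvapb, a gene of fenestrated vessels, at -0.63 in the late window, and igfbp1b, a binding protein of insulin-like growth factors, at 0.47 in the early and 0.54 in the late window.

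No vitellogenin or estrogen receptor gene with a single symbol passed the expression filter, so the list written for them gives no reading of an estrogen response. The 2 pituitary hormone genes measured were gh1, growth hormone, and avp, with a median of -0.24 in the early and 0.08 in the late window. Cardiac muscle lay within random lists against control in both windows, at 0.04 and -0.05.

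Of the tests below, the random lists of like brightness, the count of genes without another probe set, both checks for a low control reading and both checks for a high control reading were chosen only after the results had been seen. The random lists replaced a loess test planned beforehand, because that curve moved no gene by more than 0.028 in the early and 0.0488 in the late window.

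The AHR targets and other genes at least 2-fold higher in the late window formed the largest difference. Random lists as bright as the AHR targets reached at most 0.41, beside a median of 1.25 for the targets. Genes of like brightness thus did not share the difference, but these random lists had already set the targets apart. They are no separate test of scaling by brightness. The 8 other bright probe sets of 6 of these genes had a median of 1.08, though those of mao (0.48 and 0.40) and ugdh (0.62) read lower, and 14 genes, cyp1a, cyp2k18 and sult6b1 among them, had no other bright probe set, so a faulty probe set was not checked for them. Between the exposed arrays, without the control array, the AHR list differed by 1.13 (0.623 on the spike-in scale). This leaves a low control reading an unlikely source of the whole difference. The 17 genes had a median of 0.12 on the early-window array (0.62 on the spike-in scale) beside 1.35 on the late-window array. They were chosen for a late-window difference of at least 1, which fixes the 1.35 above 1 and favours low control readings. A low control reading as a source of part of the late-window difference stays open. Exposure in that window, the shorter time in clean medium, another difference between the cups or RNA samples, or a swap of the labels of the exposed arrays, which would turn which window carries the difference, remain and were not tested.

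Phototransduction genes were lower than control in both windows relative to the median gene, and on the spike-in scale their medians were 0.06 in the early and -0.22 in the late window. Less eye tissue in the early-window sample may be part of it, since 17 other retinal genes had a median of -0.18 with 14 lower. That lies between the values written down beforehand as for and against. These genes are not all particular to the retina: pax6b is also on the endocrine pancreas list. Neuronal and glial genes were lower on that array too (median -0.11, 48 of 62 lower), so a shift of neural genes in general was not told apart. Relative to the median gene the exposed arrays differed from each other by 0.27 (-0.24 on the spike-in scale), and this value does not use the control array, yet the late-window value of -0.21 against control could still come from a high control reading. Another time of day at collection was left open as well: morning and evening clock genes differed by -0.022 on the early-window array, but the spread of such a difference over random genes was 0.186. A delay in eye growth, fewer photoreceptors or lower transcript levels per cell were not told apart.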
